A study of Mus musculus with 6 samples.

How the data were processed

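Adenomas were taken from the small intestine of ApcMin mice of a mixed C57BL6/SV129 strain at 18 weeks of age, and RNA was purified with the RNeasy Plus Mini kit before library construction by a standard Illumina protocol, per the labels' protocols. The 6 libraries form 2 groups of 3, miR-34a/b/c knockout and wild-type, and each library holds RNA from a pool of 3 tumors of 1 mouse. Group and replicate number were taken from the sample titles, and the titles and genotypes were the basis for the grouping.

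The deposited values are whole-number counts per Ensembl gene with gene coordinates, in 1 table per library. TopHat2 2.1.0, HTSeq 0.6.1 and the genome build mm10 are named in the submitters' processing notes. Strand setting, treatment of reads with several alignments, annotation release and read length are not given in the sources used here. These choices matter for antisense overlaps and for near-identical copies, so such genes are given as uncertain. The tables hold 46078 genes and no summary rows. Symbols were found for 45143 identifiers in the GENCODE M21 reference, and the other 935 kept their identifier and held at most 0.256% of the counts of a library. Coordinates are those of the deposited tables, written with the first base as 1.

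Library totals ranged from 26375035 to 38354355 counts and mitochondrial genes took between 2.31% and 4.18% of them. A limit of 3 counts is used for a gene at 0, and intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries differed far beyond sampling noise (chi-square per degree of freedom between 47.0 and 263 over genes with at least 20 counts), so none was treated as a duplicate. Sex was read from Xist and from Kdm5d, Eif2s3y, Uty and Ddx3y counts and was used only as a term in an alternative fit.

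Genes were filtered with filterByExpr, which left 17254, and normalized by TMM (factors from 0.914 to 1.09). Genotypes were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test with robust fitting, with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.293. SE of a log2 fold change was taken as its size over the square root of F, and CPM values use the TMM library sizes. Fixed gene lists, written from textbook knowledge, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested (35 lists), with the estimated correlation and fry as alternatives. fry tests whether the genes of a list move, on balance, in one direction and does not compare the list with other genes. The 3′ UTR of each gene was the longest annotated in GENCODE M21, and sites for the shared miR-34 seed were CACTGCC, CACTGCCA (8mer) and ACTGCCA (7mer-A1). Copies of the called genes were sought with BLAST 2.17.0 among all GENCODE M21 transcripts at 95% identity over at least 100 bases. A first pass of this search counted genes overlapping the called gene at its own locus, which left 4 genes with no match, and these overlaps were then set apart, which left 7. Some matches and neighbouring genes are not reported here. Fisher's exact test and exact binomial intervals used scipy 1.17.1. Nearness of changed genes on the chromosomes was first tested on the 100 top genes alone, where the count did not exceed the 95th percentile of random draws, which was read as against haplotype blocks, and the neighbours of the called genes were examined afterwards. The share of epithelial cells was first tested on 3 stromal and 3 immune lists picked for their opposite shift, which was read as against it. That test was replaced by ones over all 11 lists of non-epithelial cell types. The SD among their differences came first and left it open. The lists that differed by over 2 SE in either direction came next and were read as against it, but they leave it open too. Whether genes of a list vary together was first judged by the lists passing with an estimated correlation, and then by that correlation itself, against 500 random gene sets per list matched in size and expression.

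Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Genes were named if they passed the threshold with no overlap between groups and a mean of at least 1 CPM, up to 10 per direction by fold change, and if they had the smallest p in a fixed list. The alternatives were DESeq2 size factors, library size alone, no count filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, non-robust fitting, a replicate block, a sex term, each mouse left out in turn, a fold threshold of 2, an adjusted p of 0.1, and other site classes and a matched background for the seed test. A fit on protein-coding genes only, and published miR-34 targets without members of other lists, were added after the data were seen.

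The fit was tested on simulated counts for 17254 genes in 3 against 3 libraries, with 200 genes changed. It recovered 32% of 50 genes changed by 2-fold, 64% at 4-fold, 88% at 8-fold and 90% at 32-fold, with 11 false calls among 148. A simulated change of the tuft list gave an adjusted p of 2.4e-14 with camera's preset correlation, where 2 other lists also passed, 0.0658 with the estimated one, where none did, and 0.0100 with fry, where 1 other list passed. Simulated genes were drawn independently (median estimated correlation of the lists -0.006), so recovery of lists whose genes vary together was not tested. A simulated shift of 0.15 in genes with an 8mer site was recovered as 0.138 in a test of 8mer sites. The wider main set of genes with CACTGCC was not simulated.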

Results

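Gene counts were obtained by RNA sequencing of small intestinal adenomas from 18-week-old mice carrying ApcMin, a truncating allele of the Wnt pathway regulator Apc that gives rise to many intestinal polyps. One group of 3 mice lacked miR-34a, miR-34b and miR-34c, microRNAs that share a seed sequence and are induced by p53, and the other group of 3 mice kept them. Each library was made from a pool of 3 tumors of a single mouse, so the mouse is the replicate. Library totals were 26375035, 33153025 and 38354355 counts in the knockout mice and 31340618, 33492834 and 37396224 counts in the wild-type mice. The comparison addressed which transcripts differ in ApcMin tumors when the 3 microRNAs are missing. Counts of Xist and of Y-linked genes placed 1 male mouse in each group, the second knockout replicate and the third wild-type replicate. The first principal component (40.8% of the variance) set knockout replicates 1 and 3 (scores -53.0 and -49.2) apart from knockout replicate 2 (27.1) and the 3 wild-type replicates (-0.28, 58.5 and 16.9). The share of counts on the ribosomal RNA gene CT010467.1 was lower in each knockout library (0.870%, 0.856% and 0.620%) than in each wild-type library (1.02%, 1.70% and 0.922%). As a gene it did not pass (log2 fold change -0.69 ± 0.36, adjusted p = 0.793, edgeR).

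The deleted loci came first. Mir34a (mm10 chromosome 4, 150068454 to 150068555), Mir34b (chromosome 9, 51103562 to 51103645) and Mir34c (chromosome 9, 51103034 to 51103110) had 0 counts in each of the 6 libraries. A count of 0 allows up to 3 counts, which is between 0.0782 and 0.114 CPM (library-size-scaled counts) per library. Because the short precursors were also at 0 in the wild-type mice, these rows do not check the genotype labels. Gm37795, a transcript of unclear class whose annotation overlaps the 3′ end of Mir34a (chromosome 4, 150068539 to 150070997), had 66, 40 and 51 counts in the knockout libraries and 63, 56 and 32 in the wild-type libraries. It does not check the labels either, since the extent of the deletion is not given in the sources used here.

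Of 17254 genes tested, 16 differed between genotypes, 7 of them higher and 9 lower in the knockout tumors. Slc14a1, a urea transporter (ENSMUSG00000059336, chromosome 18, 78100091 to 78142119), was the most abundant of them. It rose from 7.56 ± 3.52 CPM in wild-type to 109 ± 21.8 CPM in knockout tumors (SD, n = 3 each), a log2 fold change of 3.84 ± 0.39 (SE, adjusted p = 0.0277, edgeR). Sall4, a zinc finger transcription factor of embryonic stem cells (ENSMUSG00000027547, chromosome 2, 168748332 to 168767943), rose from 0.628 ± 0.218 to 6.15 ± 0.937 CPM, a log2 fold change of 3.29 ± 0.34 (adjusted p = 0.0277, edgeR). Gdpd3, a lysophospholipase D of the glycerophosphodiester phosphodiesterase family (ENSMUSG00000030703, chromosome 7, 126766414 to 126775643), rose from 2.24 ± 0.377 to 18.6 ± 2.19 CPM, a log2 fold change of 3.06 ± 0.21 (adjusted p = 0.00464, edgeR). An opposite-strand transcript overlaps Sall4 (Gm14261) and another overlaps Gdpd3 (Gm9967), with 6 and 157 counts over the 6 libraries. The other 4 genes that rose are annotated as processed pseudogenes, the intronless copies left by reverse transcription of an mRNA. They were Gm1840 (chromosome 8, 5639584 to 5640996, log2 fold change 4.68 ± 0.28), Pcna-ps2 (chromosome 19, 9283238 to 9284494, 5.22 ± 0.50), Gm10167 (chromosome 5, 148182899 to 148184377, 4.27 ± 0.31) and Gm4989 (chromosome X, 74566958 to 74567706). Gm4989 had 304 counts in the knockout and 3 in the wild-type libraries, a pooled ratio of 101 with an exact 95% counting interval from 34.1 to 491.

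Among the 9 genes that fell in the knockout tumors, Camk2b, a subunit of calcium/calmodulin-dependent kinase II (ENSMUSG00000057897, chromosome 11, 5969644 to 6066362), was the most abundant. It went from 28.6 ± 4.88 CPM in wild-type to 3.34 ± 0.408 CPM in knockout tumors, a log2 fold change of -3.10 ± 0.20 (adjusted p = 0.00348, edgeR). Hsd3b3, a 3β-hydroxysteroid dehydrogenase (ENSMUSG00000062410, chromosome 3, 98741523 to 98763127), fell from 11.8 ± 2.64 to 0.120 ± 0.0210 CPM, a log2 fold change of -6.57 ± 0.34 (adjusted p = 0.00298, edgeR). Hmga1b, a copy of the chromatin protein gene Hmga1 (chromosome 11, 120762794 to 120764419), fell from 10.7 ± 0.788 to 0.268 ± 0.0935 CPM (log2 fold change -5.30 ± 0.32). Zfp429, a zinc finger gene (chromosome 13, 67389309 to 67399767), had a log2 fold change of -4.39 ± 0.33, and Asb18, an ankyrin repeat and SOCS box gene (chromosome 1, 89950220 to 90014666), one of -2.85 ± 0.29. Abhd1 (chromosome 5, 30950066 to 30955091) fell by 4.42 on the log2 scale. It is uncertain, since it overlaps Preb on the opposite strand, which had 26595 counts over the 6 libraries, and the strand setting of the counting is not given in the sources used here. Hsd3b3 likewise overlaps Zfp697 on the opposite strand, with 753 counts. The remaining 3 were processed pseudogenes. Gm13443 (chromosome 2, 35340409 to 35340963) had a log2 fold change of -7.86 ± 0.56. Gm10182 (chromosome 9, 22320314 to 22321410) had 2 counts in knockout against 1116 in wild-type libraries, a pooled wild-type to knockout ratio of 561 with a counting interval from 155 to 4642. Gm12901 (chromosome 4, 123258046 to 123258904) had 3 against 369 counts, a ratio of 124 with an interval from 42.0 to 603.

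**Figure D1:**
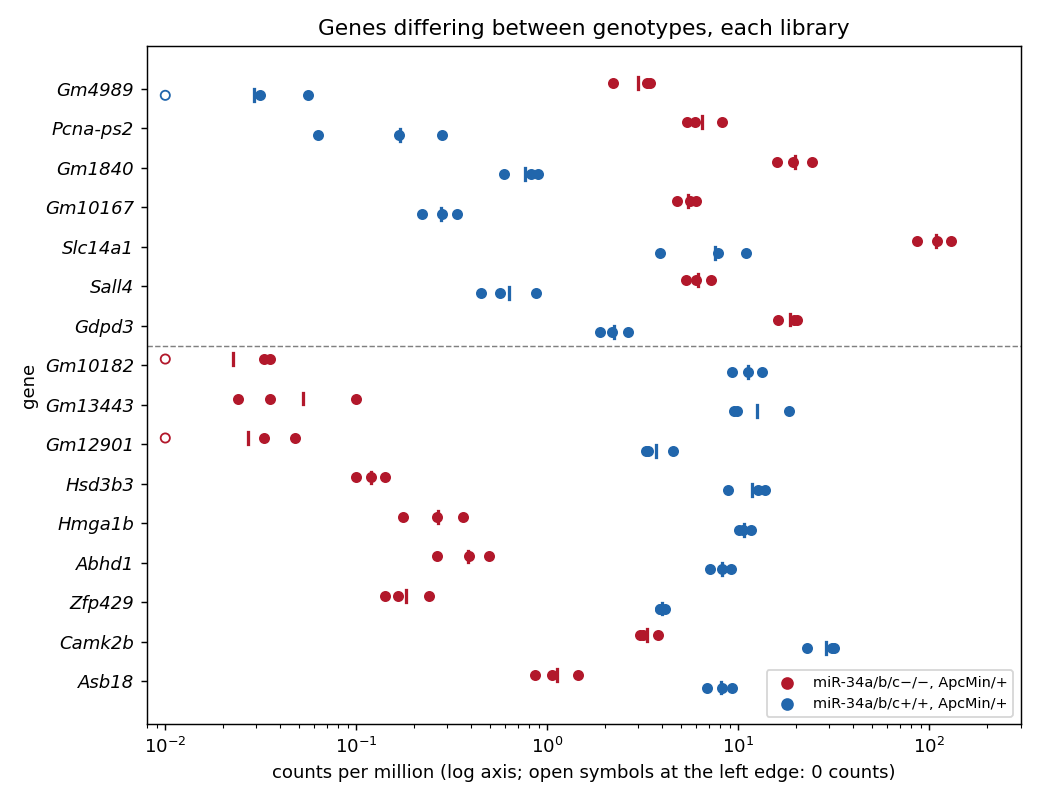
CPM on a log axis of the 16 genes that differed between genotypes, with 1 point per library, red for the 3 miR-34a/b/c knockout mice and blue for the 3 wild-type mice, vertical ticks for group means and open symbols at the left edge for libraries with 0 counts. The groups do not overlap for any of the 16 genes, and the dashed line parts the 7 genes higher in knockout tumors from the 9 lower ones.

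Processed pseudogenes made up 7 of the 16 genes (43.8%) but all pseudogene classes together only 2.92% of the genes tested (504 genes). Several have an expressed relative with which they could share reads, which makes their values uncertain. Pcna-ps2 was 99.2% identical over 781 bases to Pcna, the replication clamp, which had 104 ± 11.6 CPM in knockout and 108 ± 4.87 CPM in wild-type tumors. Gm1840 was 98.7% identical over 1046 bases to Gpi1, a glycolytic enzyme gene with 526 ± 93.8 against 603 ± 100.5 CPM. Gm13443 matched Glo1 (161 ± 11.9 against 277.5 ± 95.04 CPM) at 96.0% over 575 bases, and Gm10182 matched Hmgn2 at 97.8% over 279 bases. Hmga1b was 99.8% identical over 1602 bases to Hmga1, which had 61.8 ± 6.91 CPM in knockout and 36.6 ± 1.54 CPM in wild-type tumors (log2 fold change 0.76 ± 0.12, adjusted p = 0.245, edgeR). Hsd3b3 matched Hsd3b2, Zfp429 matched Rsl1 and Asb18 matched the transcript D10Wsu102e at 95% identity or more. Slc14a1, Camk2b, Sall4, Gdpd3, Abhd1, Gm4989 and Gm12901 had no such match outside their own locus.

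The test was edgeR's quasi-likelihood test at an adjusted p below 0.05, and 1010 genes had an unadjusted p below 0.05. The groups did not overlap for 1933 of the tested genes (11.2%), where chance gives 10%. DESeq2 called 110 genes, 46 higher and 64 lower, with all 16 among them. The count depended on single mice, with 9 genes without knockout replicate 1, 41 without knockout replicate 2, 10 without knockout replicate 3, 21 without wild-type replicate 1, 11 without wild-type replicate 2 and 29 without wild-type replicate 3. Gm1840, Gm10167, Gdpd3, Gm10182, Hsd3b3, Hmga1b and Camk2b passed in each of these 6 fits. Slc14a1 was lost without any 1 of the 3 knockout mice or wild-type replicate 1, Sall4 and Pcna-ps2 without knockout replicate 1 or 3 or wild-type replicate 2 or 3, and Asb18 in every such fit but that without knockout replicate 2. Gm4989 was lost without knockout replicate 1 or 3 or wild-type replicate 2, Gm12901 without knockout replicate 3 or wild-type replicate 2, and Gm13443, Abhd1 and Zfp429 without knockout replicate 1. With a sex term Slc14a1, Sall4, Pcna-ps2, Gm4989 and Asb18 did not pass, nor did Slc14a1 with no count filter.

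None of the 16 genes belonged to a fixed gene list, so the lists were compared as wholes. By camera with a preset correlation, 18 of 35 lists passed, 11 toward higher and 7 toward lower levels in knockout tumors, and none passed with an estimated correlation (lowest adjusted p = 0.582) or with fry (lowest adjusted p = 0.319). With an estimated correlation 2 lists, and with fry 3 lists, had an unadjusted p below 0.05. No member of any list passed over all genes tested, so members are given as values.

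Tuft cell markers, genes of the chemosensory cells of the gut epithelium, were higher in 18 of 18 tested members, with a median log2 fold change of 0.72 (adjusted p = 2.66e-09, camera). The adjusted p was 0.582 with an estimated correlation. Adjusted over the list alone, 1 member passed, Rgs13, a regulator of G protein signaling with 8.69 ± 0.443 against 3.75 ± 0.769 CPM (log2 fold change 1.21 ± 0.23, adjusted p over all genes = 0.429, edgeR). Sh2d7 had 6.26 ± 2.69 against 2.42 ± 0.273 CPM. The tuft scores of the 3 knockout libraries lay above those of the 3 wild-type libraries.

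Stromal and mast cell lists shifted upward. Fibroblast and matrix genes had a median log2 fold change of 0.74 with 25 of 28 members higher (adjusted p = 5.34e-08, camera, and 0.598 with an estimated correlation), and 0 passed when adjusted over the list alone. Pdgfra, a receptor of mesenchymal cells, had 106 ± 50.01 against 49.9 ± 20.7 CPM. Smooth muscle genes had a median of 0.62 with 17 of 19 higher (adjusted p = 1.42e-07, camera, and 0.598 with an estimated correlation), among them Des, the muscle intermediate filament desmin, with 104 ± 23.0 against 61.6 ± 22.0 CPM. Endothelial genes had a median of 0.31 with 20 of 21 higher (adjusted p = 1.18e-05, camera, and 0.598 with an estimated correlation). Flt1, a VEGF receptor, had 51.9 ± 14.3 against 30.8 ± 5.61 CPM and Vwf, the von Willebrand factor, 55.6 ± 13.3 against 30.9 ± 10.1 CPM. Genes of the epithelial to mesenchymal transition had a median of 0.56 with 21 of 24 higher (adjusted p = 1.36e-07, camera, and 0.598 with an estimated correlation), including Tgfb2 with 6.11 ± 2.19 against 2.74 ± 0.145 CPM. Mast cell genes had a median of 0.91 with 13 of 14 higher (adjusted p = 9.58e-06, camera, and 0.598 with an estimated correlation), and the protease gene Mcpt4 had 9.06 ± 3.88 against 3.97 ± 1.34 CPM. Only the smooth muscle and endothelial scores were fully separated between the groups, the former narrowly (0.19 in knockout replicate 3, 0.13 in wild-type replicate 1). The fibroblast median was 0.31 without knockout replicate 3 and 0.45 without wild-type replicate 2, and the transition median was 0.37 without knockout replicate 3. The smooth muscle median was 0.41 without knockout replicate 1 and 0.31 without wild-type replicate 2, and the mast cell median was 0.59 without knockout replicate 1, 0.46 without wild-type replicate 2 and 1.55 without wild-type replicate 3.

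Lymphoid and antigen presentation lists shifted downward. Genes of dendritic cells and MHC class II had a median log2 fold change of -0.89, with 17 of 19 members lower (adjusted p = 8.38e-13, camera), and adjusted over the list alone 9 members passed. The adjusted p was 0.582 with an estimated correlation. H2-Aa, an MHC class II chain, had 55.1 ± 26.9 CPM in knockout against 187 ± 25.9 CPM in wild-type tumors (log2 fold change -1.76 ± 0.33, adjusted p over all genes = 0.429, edgeR), and Cd74, the invariant chain, had 225 ± 118 against 666 ± 99.9 CPM. B and plasma cell genes had a median of -0.80 with 18 of 21 lower (adjusted p = 1.99e-05, camera, and 0.598 with an estimated correlation). The joining chain gene Jchain had 546 ± 263 against 1124 ± 227 CPM, whereas the immunoglobulin gene Ighg1 had 12.05 ± 6.67 against 3.75 ± 1.06 CPM. T and NK cell genes had a median of -0.46 with 24 of 27 lower (adjusted p = 0.000108, camera, and 0.598 with an estimated correlation), including the T cell receptor gene Trac with 3.43 ± 1.78 against 6.74 ± 1.01 CPM. Interferon response genes had a median of -0.55 with 36 of 38 lower (adjusted p = 1.44e-08, camera, and 0.598 with an estimated correlation), including the immunoproteasome gene Psmb8 with 29.4 ± 16.1 against 60.0 ± 18.0 CPM. Scores of the MHC class II and of the B and plasma cell lists were separated between the groups. For B and plasma cells the gap was narrow (0.137 in knockout replicate 3, 0.162 in wild-type replicate 1). Knockout replicate 2 lay within the wild-type range for the T and NK cell and the interferon lists. Without knockout replicate 2 the medians were -1.36 for MHC class II, -0.97 for T and NK cells and -1.10 for the interferon response. The interferon median was -0.18 without knockout replicate 3 and -0.30 without wild-type replicate 3, and the B and plasma cell median was -0.48 without knockout replicate 1.

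**Figure D2:**
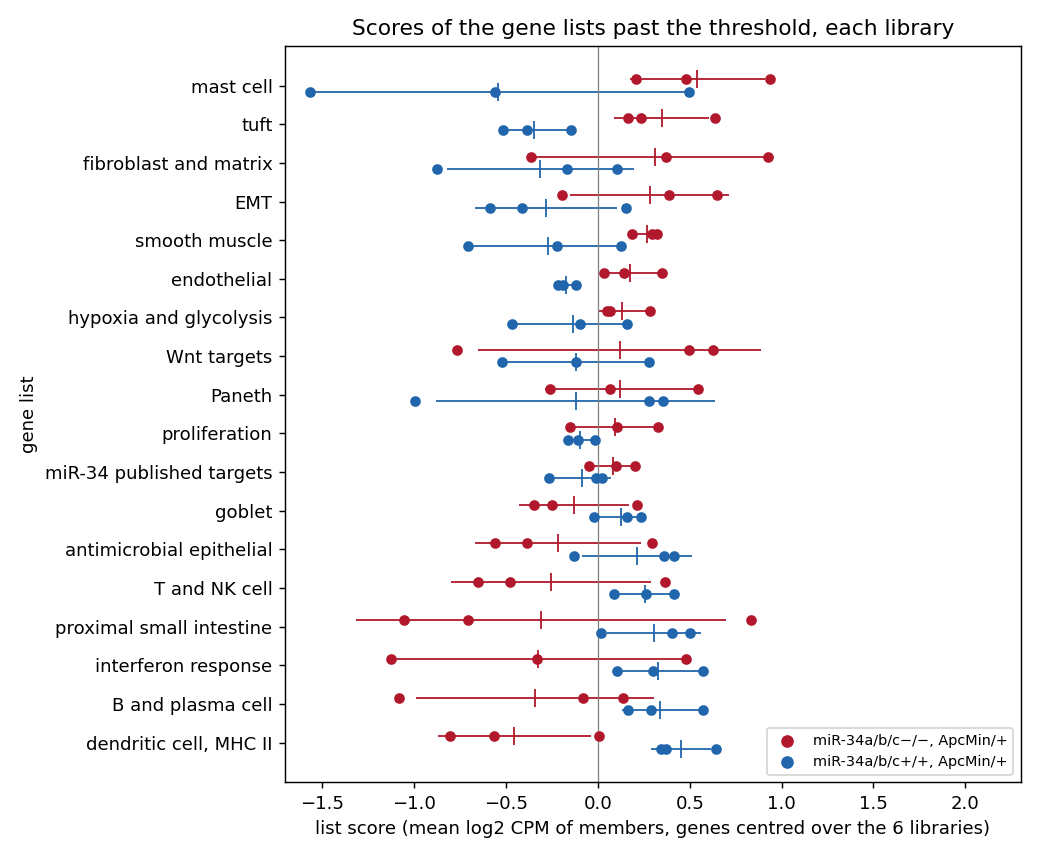
Scores of the 18 gene lists that passed camera with the preset correlation, as the mean log2 CPM of the members after centring each gene over the 6 libraries, with 1 point per library, vertical ticks for group means and horizontal bars for the SD (n = 3), red for knockout and blue for wild-type mice. For 5 of the lists (tuft, smooth muscle, endothelial, dendritic cell and MHC II, B and plasma cell) the groups do not overlap. These are the only ones among the 35 lists tested, where chance gives 10%.

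Epithelial lists moved in both directions. Goblet cell genes had a median log2 fold change of -0.20 with 15 of 19 lower (adjusted p = 0.0136, camera), antimicrobial epithelial genes -0.38 with 20 of 24 lower (adjusted p = 0.0116, camera), and proximal small intestine genes -0.29 with 11 of 12 lower (adjusted p = 0.0160, camera). With an estimated correlation these adjusted p were 0.598, 0.598 and 0.641. Zg16, a mucus protein gene of goblet cells, had 661 ± 370 against 1083 ± 161 CPM. Paneth cell genes had a median of 0.23 with 14 of 19 higher (adjusted p = 0.0169, camera, and 0.598 with an estimated correlation). The antimicrobial gene Ang4, which is in both the Paneth and the antimicrobial list, had 166 ± 142 CPM in knockout and 25.1 ± 9.80 CPM in wild-type tumors (log2 fold change 2.73 ± 0.65, adjusted p = 0.762, edgeR), and the lectin Itln1 had 261 ± 89.6 against 133 ± 24.1 CPM. The goblet and proximal small intestine lists no longer passed without knockout replicate 1, knockout replicate 3 or wild-type replicate 3. The Paneth list was lost without knockout replicate 1 or wild-type replicate 1, and the antimicrobial list without knockout replicate 1 or wild-type replicate 3. Medians moved with single mice. The goblet median was -0.37 without knockout replicate 2 and -0.13 without wild-type replicate 3, and the antimicrobial median was -0.22 and -0.75 without knockout replicates 1 and 2 and -0.61 and -0.20 without wild-type replicates 1 and 3. The proximal small intestine median was -0.02, -0.83 and -0.16 without knockout replicates 1, 2 and 3 and -0.45 without wild-type replicate 1, and the Paneth median was 0.34 and 0.13 without knockout replicates 2 and 3 and 0.06 and 0.36 without wild-type replicates 1 and 2.

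Proliferation genes had a median log2 fold change of 0.21 with 34 of 37 higher (adjusted p = 0.000127, camera, and 0.673 with an estimated correlation). Mki67, the proliferation antigen, had 225 ± 9.46 against 178 ± 5.51 CPM. Hypoxia and glycolysis genes had a median of 0.22 with 21 of 24 higher (adjusted p = 0.000197, camera, and 0.598 with an estimated correlation), including Bnip3, a hypoxia-induced mitophagy receptor, with 45.1 ± 2.25 against 25.1 ± 8.55 CPM. Wnt target genes had a median of 0.29 with 23 of 25 higher (adjusted p = 0.0340, camera, and 0.823 with an estimated correlation), and cyclin D1 (Ccnd1) had 139 ± 16.4 against 111 ± 9.88 CPM. The Wnt call was lost in 4 of the 6 fits that left out a mouse (knockout replicates 1 and 3, wild-type replicates 2 and 3) and with library size alone, limma-voom or a sex term. The Wnt median was 0.13, 0.61 and 0.07 without knockout replicates 1, 2 and 3 and 0.45 and 0.15 without wild-type replicates 1 and 2. The proliferation call was lost without knockout replicate 1 (median 0.11), and the hypoxia call without wild-type replicate 1 (median 0.10, and 0.39 without wild-type replicate 3).

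Published miR-34 targets, as listed from textbook knowledge, had a median log2 fold change of 0.14, with 31 of 41 higher and 0 passing when adjusted over the list alone (adjusted p = 0.0174, camera, and 0.598 with an estimated correlation). The receptor kinase gene Axl had 45.0 ± 10.3 against 28.2 ± 6.40 CPM (log2 fold change 0.67 ± 0.23, adjusted p = 0.793, edgeR), and the chromatin gene Hmga2 had 12.7 ± 2.56 against 7.62 ± 2.68 CPM. The call was lost without knockout replicate 3 (median 0.07) or wild-type replicate 2, and the median was 0.26 without knockout replicate 2. It was also lost without the 16 members shared with other lists, where the other 25 had a median of 0.08 (adjusted p = 0.392, camera). Among the shared members were Pdgfra (log2 fold change 1.08 ± 0.43) and Pdgfrb (0.72 ± 0.30) of the fibroblast, Snai1 (0.55 ± 0.48) of the transition and Kit (0.52 ± 0.34) of the mast cell list. Across the transcriptome, the 2460 tested genes with a site for the shared seed (CACTGCC) in the longest annotated 3′ UTR had a median log2 fold change of 0.06, and the 12286 without one a median of 0.01. The difference of 0.049 did not pass (p = 0.0560, camera), and p was 0.196 with an estimated correlation. Of 209 shuffled 7-mers of the same bases, 61 gave a difference at least as large, and of the 89 without CG, which the seed site lacks too, 15 did. Against genes matched on 3′ UTR length and expression the difference was -0.00010. The difference passed without knockout replicate 1 (0.069), without wild-type replicate 1 (0.064), with library size alone (0.044) and with the weaker 7mer-A1 sites added (0.054). With those sites p was 0.207 with an estimated correlation, and the difference from matched genes was 0.00081.

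The other 17 lists did not pass. For Notch pathway genes (adjusted p = 0.110, camera), adjusted over the list alone 1 member passed, the ligand Jag2, with 20.6 ± 2.19 against 10.9 ± 1.41 CPM. For enteric nerve and glia genes (adjusted p = 0.0968, camera) it was the glial marker S100b with 1.10 ± 0.112 against 2.54 ± 0.171 CPM, and for macrophage genes (adjusted p = 0.544, camera) the lipopolysaccharide co-receptor Cd14 with 19.4 ± 1.17 against 28.5 ± 0.683 CPM. Intestinal stem cell genes (adjusted p = 0.237, camera) included Prom1 with 854 ± 174 against 489 ± 112 CPM, p53 targets (adjusted p = 0.404, camera) included Zmat3 with 43.7 ± 5.26 against 33.9 ± 3.25 CPM, and fetal and regenerative genes (adjusted p = 0.344, camera) included Ankrd1 with 0.827 ± 0.371 against 0.259 ± 0.0877 CPM. Inflammatory cytokine genes (adjusted p = 0.404, camera) included Ptgs2, the inducible cyclooxygenase, with 40.6 ± 22.5 against 14.0 ± 8.20 CPM, and enteroendocrine genes (adjusted p = 0.858, camera) the peptide YY gene Pyy with 4.88 ± 3.72 against 17.6 ± 5.16 CPM. Enterocyte genes (adjusted p = 0.544, camera) included sucrase-isomaltase, Sis, with 934 ± 630 against 397 ± 180 CPM. For the enterocyte, adipocyte and neutrophil lists the median, the mean and the test did not all have one sign. Adjusted p by camera was 0.187 for apoptosis, 0.240 for epithelial adhesion, 0.318 for the early response to dissociation, 0.392 for pancreas, 0.404 for cholesterol synthesis, 0.755 for distal small intestine and colon, 0.876 for adipocyte and 0.931 for neutrophil genes.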

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

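The protein-coding fit and the miR-34 targets without members of other lists (median 0.08 against 0.14, adjusted p = 0.392, camera) were chosen after seeing the data, and the other settings before. The 16 named genes kept their direction in each setting in which they were tested. As they were named for having no overlap between the groups, this was largely fixed beforehand. Of their 248 alternative values, 215 stayed past the threshold. The 18 lists that passed kept their direction in all 307 alternative values, of which 249 stayed past the threshold. Genes higher in knockout numbered 7 and genes lower 9. DESeq2's Wald test gave 46 and 64, with an adjusted p of NA for 22 genes. The sex term gave 3 higher genes and protein-coding genes alone gave 3 higher and 5 lower, where fewer genes were tested and 8 of the 16 could not be. Leaving out 1 mouse gave 3 to 10 higher and 5 to 31 lower genes, the latter without knockout replicate 2, and 12 to 22 lists. Apart from fewer genes or mice, the cause of these differences was not tested. At an adjusted p of 0.1, 19 genes passed.

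Of the 18 lists, 0 passed with an estimated correlation and 0 with fry. The seed site difference of 0.049 ranged from 0.029 to 0.069 with a mouse left out. It passed the threshold with library size alone at 0.044 and with 7mer-A1 sites added at 0.054, and turned to -0.00010 against genes matched on 3′ UTR length and expression; the cause was not tested. Of the 17 lists that did not pass, 10 passed in at least 1 alternative.

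Whether replicate numbers pair the mice cannot be told from so few mice. Correlations of deviations between mice of the same number were 0.22, 0.27 and 0.08. Those between mice of different numbers ran from -0.30 to 0.18, the highest for knockout replicate 3 with wild-type replicate 1. With the replicate block 14 genes (6 higher, 8 lower) and 18 lists passed, and Gm4989 and Asb18 did not. Depth limits low genes, since a single count is a large share of the value of the nearly silent copies, and 32% of simulated 2-fold changes were recovered, so changes of that size or smaller can be missed.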

Other observations

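The genes and tests in this part were chosen after the results were seen, except the tests of other splits for genes, of sequence near the deleted loci and of seed sites. Just outside the threshold were Unc5a, a netrin receptor gene (log2 fold change -3.50 ± 0.41, adjusted p = 0.0598, edgeR), 2200002J24Rik (-6.16 ± 0.74, adjusted p = 0.0616) and the pseudogene Rbpj-ps3 (6.08 ± 0.77, adjusted p = 0.0850). Beside Hsd3b3 on chromosome 3, Hsd3b2 had 1.31 ± 0.322 CPM in knockout and 3.85 ± 0.721 CPM in wild-type tumors (log2 fold change -1.55 ± 0.30, adjusted p = 0.460, edgeR). Beside Camk2b, the myosin light chain gene Myl7 had 10.5 ± 2.04 against 31.4 ± 11.3 CPM, and beside Slc14a1 the sialyltransferase gene St8sia5 had 7.94 ± 2.21 against 1.55 ± 0.728 CPM, neither passing (adjusted p = 0.408 and 0.342, edgeR). Wnt10b, a Wnt ligand, had 0.446 ± 0.138 against 0.0998 ± 0.0105 CPM, and Irx5, a homeobox gene, 3.67 ± 2.16 against 0.532 ± 0.264 CPM (adjusted p = 0.581 for both, edgeR). Of 7 immunoglobulin variable genes among the 100 smallest p, 6 were lower in knockout tumors, among them Ighv1-76 at 0.194 ± 0.0404 against 3.22 ± 2.08 CPM, and Igkv4-90 alone was higher, at 3.88 ± 3.42 against 0.256 ± 0.121 CPM.

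The first pattern is the set of 16 genes itself. The real split called 16 genes and the highest of the other 9 splits of the 6 libraries called 5, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Sequence carried along within 10 Mb of the deleted loci is argued against as the source of the set. Of the 16 genes, 0 lay within 10 Mb of Mir34a or Mir34b/c, where 2.39% of the tested genes lie (one-sided Fisher exact p = 1.0). Gm12901 and Gm10182 lie farther off on the same chromosomes as the loci (4 and 9), so a longer segment is not excluded for them. The other called genes lie on other chromosomes. For lost repression through seed sites, the shift of all tested genes with a site was at percentile 70.8 of the shuffled 7-mers (83.1 of those without CG). That shift covers genes across the transcriptome and does not decide the cause of the 16 calls. Lost repression of a gene through its own sites would raise it, which argues against it for the 9 genes lower in the knockout. Of the 3 called genes that rose and have an annotated 3′ UTR, 1 held a site, Slc14a1. So few genes cannot be set against the 2460 tested genes with a site and the 12286 without. For Slc14a1 direct repression stays open, and for the others indirect effects of the genotype were not tested.

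The second pattern is that many of the 16 genes were nearly silent in one genotype, with 7 processed pseudogenes among them. The search for near-identical copies covered annotated transcripts at 95% identity over at least 100 bases. Copies outside that limit were not sought, which leaves Gm4989 and Gm12901, processed pseudogenes without a match, less certain. Reads shared with copies within that limit cannot explain the 7 genes with none elsewhere, Slc14a1 and Camk2b among them. For 2 genes, Hsd3b3 and Zfp429, the copies were lower along with them, which argues against reads moved from these genes to their copies. Reads left out for having several alignments could lower both, and their treatment is not given, so shared reads are not excluded there. For the other 7 the explanation stays open. In 6 of these, Hmga1b among them, the copies differed in the opposite direction. In Gm13443 its copy Glo1 was also lower (161 ± 11.9 against 277.5 ± 95.04 CPM), but with a spread in which the 12.5 CPM lost by Gm13443 could go unseen. Strain variants are a candidate explanation, as the mice are of a mixed background and the groups could carry different alleles or retrocopies, and Nnt, in which C57BL/6J carries a deletion, had 37.1 ± 2.06 against 63.9 ± 11.1 CPM (adjusted p = 0.429, edgeR). Haplotype blocks cannot be told apart from the genotype, and a variant of a single gene needs no changed neighbour. Of the 100 top genes, 23 lay within 1 Mb of another, or 14 with 1 gene per family. In a permutation test, random draws of genes averaged 14.6 with a 95th percentile of 23 (p = 0.0542), and other splits reached 35. Among the called genes' neighbours, 5.03% had an unadjusted p below 0.05 (random median 5.74%). Near-identical copies such as Hsd3b2 were left out around the called genes but not around the random ones, so these shares are not fully alike.

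The third pattern is that fixed lists of non-epithelial cell types went apart, with fibroblast, smooth muscle, endothelial and mast cell lists higher and dendritic and MHC class II, B and plasma cell, and T and NK cell lists lower in knockout tumors. The 11 such lists are these 7 and the macrophage, neutrophil, enteric nerve and glia, and adipocyte lists. A lower share of epithelial cells would raise all 11 if the other cell types kept their proportions to one another. Of these, 4 were lower, 1 of them by over 2 SE (dendritic and MHC class II, score difference -0.91 ± 0.26). Endothelial (0.35 ± 0.10) and smooth muscle (0.54 ± 0.25) were higher by over 2 SE, and 0 other splits had lists past 2 SE both ways. The test leaves such a share open as the whole cause, since its 1 list lower by over 2 SE is of mixed content. In that list log2 fold changes were -1.76 for H2-Aa, -1.56 for Cd74, -1.64 for Xcr1 and -0.85 for Itgax. They were -0.10 for Flt3, -0.20 for Batf3 and 0.22 for Zbtb46. The other lower lists (B and plasma cell -0.68 ± 0.39, T and NK cell -0.51 ± 0.33, adipocyte -0.03 ± 0.11) lay within 2 SE. The 11 lists do not bear on a lower epithelial share that comes with changed proportions among the other cell types. The epithelial adhesion list had a score difference of -0.07 and did not pass (adjusted p = 0.240, camera). Genes of a list varying together between mice may account for the calls. In 18 of the 18 called lists the genes correlated within genotypes (0.139 to 0.706) above 95% of random gene sets, where camera's preset is 0.01. This does not mark out the called lists, since lists that did not pass also correlated (enterocyte 0.683, neutrophil 0.665). The 0 lists called with an estimated correlation decide nothing, as that test missed a simulated 2-fold change of the tuft list. The 0 called with fry decide nothing either. It recovered that change, but among genes simulated without correlation (median -0.006). The real split called 18 lists and the highest other 24, so 5 of the 10 splits called as many, the SD among the 11 differences (0.59) was reached in another split (0.61), and 10 splits are too few for a share under 0.05. An effect of the genotype on these cell types stays open.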
